A study of Mus musculus with 18 samples.

How the data were processed

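RNA was measured on 18 Affymetrix Mouse Gene ST arrays from bone marrow-derived macrophages, which are macrophages grown from marrow precursors. The cells were wild type (WT) or lacked tristetraprolin (TTP, encoded by Zfp36; KO), and each of the 6 combinations of genotype and time was represented by 3 arrays. The labels' protocols state treatment with lipopolysaccharide (LPS) followed by actinomycin D, which blocks transcription, and SB203580, an inhibitor of the kinase p38, for 0, 45 or 90 min. The time without transcription and the time with the p38 inhibitor were therefore the same variable.

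Per the submitters' processing notes, the authors used RMA in Affymetrix Expression Console, whose versions are not given in the sources used here. The deposited values are intensities on a linear scale, as inferred from their range, with array medians of 7.41 to 8.19 and array maxima of 7379 to 14337. RMA brings all arrays to a shared distribution of signals. A change over time is thus relative to the average mRNA on the array, and a general loss of RNA after the transcription block is not visible. For arrays, the number of replicates limits the precision; the file holds no detection calls.

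The log2 of each intensity was taken with no offset. Of 25138 rows, 21039 had 1 gene symbol in the platform annotation, 1485 had several and 2614 were not listed there; rows with several symbols or none were not named. Symbols were updated through gene identifiers in a RefSeq table of assembly GRCm38.p6, and 84 rows kept their older symbol. For each symbol the row with the highest mean over all arrays was kept, which left 19454 genes. Genes whose highest group mean reached the median row mean, a log2 intensity of 3.03 or an intensity of 8.16, were tested, 10258 in all. A fall that ends near or below this signal limit is limited by background and understates the loss.

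Group means were fitted with limma 3.58.1 in R 4.3.3 over all 18 arrays without a block, with empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison at 0.05. A decay difference is the log2 change from 0 min in KO minus that in WT. Unstable genes were those whose mean log2 change over both genotypes at 90 min was -1 or lower at an adjusted p below 0.05. Relative half-lives came from a straight line over the 3 times, with 95% confidence intervals. Errors of log2 changes are SE from the model with n = 3 arrays per group, unless SD is stated. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists with enough measured genes, and again with an estimated correlation. Zfp36 was named first. Named genes were then the 10 largest changes in each direction among genes past the threshold with separated groups (5 at 45 min), up to 4 members per list past the threshold or the 2 largest if none passed, and the reported TTP targets for the decay difference at 90 min. Genes with provisional names were counted but not named.

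The labels do not state that the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. No replicate pair held identical values, and correlations within groups were 0.940 to 0.993. The sample numbers in the titles fall into 2 runs. Replicate 3 of every group has the lower numbers (series A), and replicates 1 and 2 have the higher numbers (series B). The first principal component, with 29.0% of the variance, ran from 11.97 to 30.9 in series A and from -23.1 to -5.76 in series B. The series was therefore treated as a possible technical batch, as a block and within series B; series A has 1 array per group and gives values without a test.

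Replicate numbers are shared between groups. Same-numbered arrays deviated together, with every correlation of deviations from the group means above 0.1, for KO at 90 min against 0 min (0.413 to 0.694), WT at 45 min (0.333 to 0.550), KO at 45 min (0.321 to 0.677) and KO against WT at 0 min (0.156 to 0.369). For these comparisons the numbers were taken to pair the samples. The first count given for them is from the planned fit without a block, and the replicate block gives the paired count. The numbers were not taken to pair the samples for WT at 90 min (lowest -0.287) or the decay differences (lowest -0.287 at 90 min and 0.018 at 45 min).

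The procedure was tested on simulated data with 200 changed genes among 10258. Noise was normal and independent for each gene, without the series or replicate structure of the real arrays. For the decay difference at 90 min it recovered 34.2% of genes changed by a log2 of 1, 82.7% of those changed by 2 and 98.6% of those changed by 4. For WT at 90 min the shares were 75%, 98.6% and 100%. False genes made up 5.41% of the calls for the decay difference at 90 min and 7.5% for WT at 90 min. The real arrays carry shared structure and gave fewer calls, so recovery there may be lower. Alternatives covered blocks, filters, probe rows, scaling, variance models, thresholds, a straight line over time and omission of arrays or replicate numbers. Array weights were planned as well, but their estimate did not converge. A correction for gene span, an offset of 16, WT at 0 min represented by replicate 3 alone, the genotype difference averaged over the 3 times and, for it, the 3 arrays of a genotype and number taken as a set were added after the data had been seen. No genome sequence was used, so 3' UTR motifs were not analysed here.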

Results

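The arrays covered WT and TTP-deficient macrophages stimulated with LPS and then followed for 0, 45 and 90 min after transcription was blocked in the presence of a p38 inhibitor. Each of the 6 groups held 3 arrays, and the 18 array medians lay between intensities of 7.41 and 8.19. The series addresses which mRNAs depend on TTP for their decay. TTP binds AU-rich elements in 3' untranslated regions and recruits deadenylases, and p38 signalling restrains this activity, which is the stated reason for inhibiting p38.

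Zfp36, the targeted gene, lies on chromosome 7 from 28376784 to 28379228 (GRCm38.p6). At 0 min its log2 intensity was 7.64 ± 0.45 (SD, n = 3) in WT and 6.61 ± 0.31 (SD, n = 3) in KO, a difference of -1.04 ± 0.32 with a limma adjusted p of 0.564. The difference was -1.70, -1.11 and -0.31 in replicates 1, 2 and 3, and within series B it was -1.40 with an adjusted p of 0.0149. The array reports the gene as a whole, and the part deleted in the KO was not identified here. A signal from the remaining transcript is therefore possible, and the measurement does not check the genotype labels. Zfp36 mRNA fell by 3.52 ± 0.32 on the log2 scale in WT over 90 min.

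In WT macrophages, Tnf, which encodes the cytokine TNF, fell by 4.24 ± 0.18 on the log2 scale over 90 min, leaving 5.31% of its signal. Socs3, an inhibitor of cytokine receptor signalling, fell by 3.66 ± 0.49, and the kinase gene Plk2 fell by 3.57 ± 0.43. Nfkbia fell by 3.38 ± 0.49 and Tnfaip3 fell by 3.21 ± 0.39, both feedback inhibitors of NF-kB. The phosphatase gene Dusp1 fell by 3.39 ± 0.67 and Dusp2 fell by 3.17 ± 0.29, Tnfsf9 fell by 3.10 ± 0.31 and the neutrophil chemoattractant Cxcl1 fell by 2.82 ± 0.35. Rbis, which acts in ribosome biogenesis, was the only gene that rose, by 1.36 ± 0.18. In all, 125 genes fell and 1 rose among 10258 (limma, Benjamini-Hochberg). With the title-number series as a block 291 fell and 10 rose. Within series B 613 fell and 765 rose, and of those 1378 genes 422 had the same sign in series A. All 126 genes were also called with the series block and 125 of them within series B.

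The counts for WT at 90 min moved with single arrays. Without WT 0 min replicate 3, 163 genes rose. Without WT 0 min replicate 1 or 2, WT 90 min replicate 1, 2 or 3, KO 0 min replicate 1, KO 45 min replicate 2 or 3, or KO 90 min replicate 1, 2 or 3, between 2 and 5 rose. The genes that fell numbered 80 without WT 0 min replicate 2, 68 without WT 90 min replicate 1 and 82 without WT 90 min replicate 2. Among the named genes Dusp1 lost its call in 2 of 18 omissions of a single array, Csrnp1 in 3, Il23a in 4 and Mcl1 in 2. At 90 min in WT the log2 signal was 3.89 for Dusp1, 3.44 for Dusp2, 3.27 for Csf2, 3.77 for Ier3, 3.18 for Il23a and 2.35 for Zfp87, within 1 of the signal limit of 3.03 or below it, so background limits these falls.

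Of 19 measured mRNAs on a list of reported TTP targets, which includes Zfp36 itself, 8 fell in WT over 90 min (13 adjusted over the list alone). Among them Csf2 fell by 2.24 ± 0.32 and Cxcl2 by 1.98 ± 0.23. The list median was -1.08, with -1.27 in series A and -0.85 in series B (camera adjusted p 5.46e-21, and adjusted p = 0.000190 with an estimated correlation). Among 21 immediate early genes, which are induced without new protein synthesis, 9 fell (9 adjusted over the list alone). Junb fell by 2.43 ± 0.38, Ier3 fell by 2.21 ± 0.38 and Csrnp1 fell by 2.16 ± 0.43 (list median -0.62, adjusted p 1.52e-11, and adjusted p = 0.0158 with an estimated correlation). Of 21 cytokines 4 fell (9 adjusted over the list alone), and Il23a fell by 0.74 ± 0.16 (list median -0.51, adjusted p 5.41e-08, and adjusted p = 0.000515 with an estimated correlation). Of 13 survival and apoptosis regulators 3 fell (6 adjusted over the list alone). The kinase gene Pim1 fell by 1.24 ± 0.18, Gadd45b fell by 1.24 ± 0.18 and the anti-apoptotic Mcl1 fell by 1.11 ± 0.22 (list median -0.68, adjusted p 1.77e-05, and adjusted p = 0.0158 with an estimated correlation).

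Further lists were lower as sets in WT at 90 min at the preset correlation. NF-kB feedback genes (3 of 17 fell, 7 adjusted over the list alone) had a median of -0.46, chemokines (2 of 17, 5 adjusted over the list alone) -0.24, and MAP kinase phosphatases with Sprouty genes (2 of 12, 4 adjusted over the list alone) -0.39. Cell cycle genes (1 of 29, the mitotic kinase gene Aurka) had a median of -0.25 and numbered zinc finger genes (5 of 139, 11 adjusted over the list alone) -0.19; Zfp87 fell by 1.63 ± 0.26. For these lists the adjusted p with an estimated correlation were 0.0646, 0.195, 0.0646, 0.628 and 0.226. With the series as a block and an estimated correlation the phosphatase and Sprouty list passed (adjusted p 0.0464). Fibroblast markers (8 measured, 0 past the threshold) were higher as a set with a median of 0.19 (adjusted p 0.00215, and adjusted p = 0.237 with an estimated correlation). The Aurka call was lost in 12 of 18 omissions of a single array.

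In KO macrophages 23 genes fell over 90 min and 0 rose in limma, against 160 with a higher signal at an unadjusted p below 0.05. Dusp2 fell by 2.81 ± 0.29, Socs3 fell by 2.55 ± 0.49, Tnfaip3 fell by 2.49 ± 0.39 and Plk2 fell by 2.36 ± 0.43. Clec2d, which encodes a ligand of a natural killer cell receptor, fell by 2.13 ± 0.28, and the linker histone gene H1f5 fell by 2.06 ± 0.33. Tiparp fell by 1.83 ± 0.36, Edn1 (endothelin 1) fell by 1.72 ± 0.26 and the kinase gene Map3k8 fell by 1.65 ± 0.29. The log2 change of Tnf was -0.45 ± 0.18, that of Cxcl1 -0.18 ± 0.35 and that of Cxcl2 0.11 ± 0.23, none past the threshold.

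With the replicate number as a block 56 genes fell in KO at 90 min and 1 rose, with the series as a block 60 and 1, and within series B 22 and 0; all 22 had the same sign in series A. Without KO 90 min replicate 2, 63 genes fell, and without replicate 1 or 3 of that group 3 and 2. Without KO 0 min replicates 1, 2 and 3 the counts were 6, 7 and 3, without WT 0 min replicates 2 and 3 they were 13 and 39, without WT 45 min replicates 1 and 2 they were 13 and 12, and without WT 90 min replicate 1 the count was 13. Without WT 90 min replicate 2, 1 gene rose. Dusp2 and Clec2d were past the threshold in all 18 omissions of a single array, whereas Socs3 was not in 12, Plk2 in 9, Tiparp in 14, Zfp36 in 14, and Tnfaip3, H1f5, Edn1, Map3k8, Gadd45b, Zfp217 and Zfp87 in 4, 4, 3, 5, 4, 3 and 5.

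As sets, immediate early genes, MAP kinase phosphatases with Sprouty genes, survival regulators and numbered zinc finger genes were lower in KO at 90 min than at 0 min. Past the threshold were 1 of 21 immediate early genes (Plk2; 7 adjusted over the list alone), 1 of 12 phosphatases (Dusp2; 3 adjusted over the list alone) and 1 of 13 survival regulators (2 adjusted over the list alone), where Gadd45b fell by 1.13 ± 0.18. Of 139 zinc finger genes 2 passed (11 adjusted over the list alone), and Zfp217 fell by 1.64 ± 0.27 and Zfp87 fell by 1.45 ± 0.26, to signals of 3.92 and 2.75 near or below the limit of 3.03. The medians of these lists were -0.54, -0.29, -0.25 and -0.27, and their adjusted p with an estimated correlation were 0.0409, 0.0409, 0.0313 and 0.0458. The call of the immediate early genes was lost with an estimated correlation and a block, with an adjusted p of 0.0996 for the replicate block and 0.0728 for the series block. The reported TTP targets had a median of -0.18, with 1 of 19 past the threshold (4 adjusted over the list alone), Zfp36, which fell by 1.61 ± 0.32 (camera adjusted p 0.000693, and adjusted p = 0.0586 with an estimated correlation). Other lists called at the preset correlation were lost with an estimated correlation. Among those with a lower signal, cytokines (median -0.12) had an adjusted p = 0.0586 with an estimated correlation, NF-kB feedback genes (-0.25) 0.130, deadenylation and decay genes (-0.13) 0.491, cell cycle genes (-0.11) 0.639 and p53 targets (-0.12) 0.130. Among those with a higher signal, antigen presentation genes (median 0.30) had an adjusted p = 0.127 with an estimated correlation, fibroblast markers (0.17) 0.491 and respiratory chain genes (0.05) 0.342.

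The direct question of the series is the difference between the genotypes in how far each mRNA fell. At 90 min the decay difference was 3.79 ± 0.26 for Tnf (limma adjusted p 3.76e-07) and 2.09 ± 0.33 for Cxcl2, a neutrophil chemoattractant (adjusted p 0.0375). Per replicate number it was 3.61, 4.10 and 3.67 for Tnf and 1.98, 1.53 and 2.76 for Cxcl2. Fitted as a straight line, the relative half-life of Tnf mRNA was 21.2 min in WT (95% interval 19.5 to 23.4) and 202 min in KO (108 to 1631). For Cxcl2 it was 45.4 min in WT (36.5 to 60.2), and in KO the slope was not below 0, with a lower limit of 239 min. These half-lives are relative to the average mRNA on the array.

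**Figure D1:**
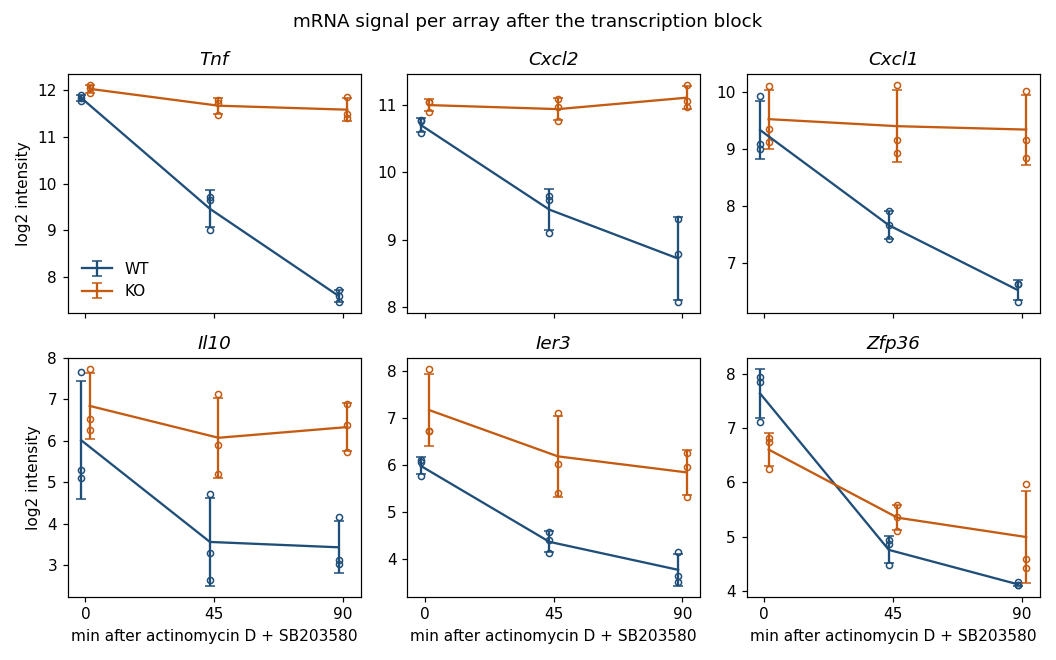
Log2 intensity (y axis) against minutes after addition of actinomycin D and SB203580 (x axis) for 6 genes in WT (blue) and KO (orange); circles are single arrays, and lines join group means with SD bars (n = 3). Tnf in WT goes from 11.84 to 7.60 while in KO it goes from 12.03 to 11.58; Il10, Ier3 and Zfp36 are shown for their spread, and their decay differences did not pass the threshold.

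These 2 genes were the only ones past the threshold at 90 min in limma, and 0 genes had a larger loss in KO, against 177 with a positive and 97 with a negative difference at an unadjusted p below 0.05. With the series as a block 3 genes passed, the additional one being Cxcl1, with a decay difference of 2.64 ± 0.50 (adjusted p 0.190 without the block and 0.00113 with it) and 2.28, 2.09 and 3.54 per replicate number. Within series B 5 genes had a positive and 2 a negative difference, all 7 with the same sign in series A. Across all genes, which are not independent replicates, the correlation of this difference between the 2 series was -0.34. The Tnf call was kept in all 37 settings run. The Cxcl2 call was kept in 12 of 37 settings, with a difference of 1.76 to 2.38 and an adjusted p of 0.00161 to 0.9996. Among omissions of a single array it was kept without WT 45 min replicate 3 and without WT 90 min replicate 2 or 3, and was lost when any of the other 15 arrays was left out, with a highest adjusted p of 0.153 without WT 0 min replicate 1, which left 1 gene. It was also lost with centring on ribosomal protein genes (adjusted p 0.394) or housekeeping genes (0.311), where Cxcl2 had 1.99 and 1.93. Without WT 90 min replicate 3, 1 gene had a negative difference.

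The reported TTP targets had decay differences above those of the other tested genes as a set: 17 of 19 were positive, with a median of 0.71 (0.85 in series A and 0.60 in series B). Of these, 2 passed over all genes tested and 7 adjusted over the list alone (camera adjusted p 8.92e-15, and adjusted p = 0.00107 with an estimated correlation). Short-lived mRNAs in general also leaned this way. Of the 92 unstable genes described below, some of them on this list, 83 were positive, with a median of 0.48. A positive sign is thus not particular to the list, which was not tested against unstable genes alone. The 19 include Zfp36, the targeted gene, at 1.91 (limma adjusted p 0.758), whose signal in KO may come from a remaining transcript. Values for other members that did not pass were 2.08 ± 0.94 for Il10, 1.30 ± 0.46 for Csf2, 1.19 ± 0.76 for Il6, 1.07 ± 0.63 for Ccl2 and 0.89 ± 0.54 for Ier3, whereas Vegfa had -0.07 ± 0.39 and Fos -0.36 ± 0.38. In WT at 90 min Il10 (3.43), Csf2 (3.27), Fos (3.56) and Ier3 (3.77) were near the signal limit of 3.03, as were Csf2 (3.59) and Fos (3.74) in KO, so background limits these 4 differences. Cytokines had a median of 0.40 (0.71 in series A and 0.44 in series B) with 1 of 21 past the threshold and 2 adjusted over the list alone (adjusted p 2.57e-05, and adjusted p = 0.00314 with an estimated correlation). Chemokines had a median of 0.29 (0.86 in series A and 0.17 in series B) with 1 of 17 past the threshold and 3 adjusted over the list alone (adjusted p 2.57e-05, but adjusted p = 0.278 with an estimated correlation). The passing cytokine and chemokine genes, Tnf and Cxcl2, are also reported TTP targets, so these lists are not separate evidence. NF-kB feedback genes and immediate early genes had no member past the threshold. Their medians were 0.29 and 0.11, and their adjusted p of 0.0274 and 0.0413 became an adjusted p = 0.760 for both with an estimated correlation. In series A these 2 medians were -0.22 and -0.01, and the shift of -0.16 under centring on housekeeping genes exceeds the size of the latter over all arrays.

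**Figure D2:**
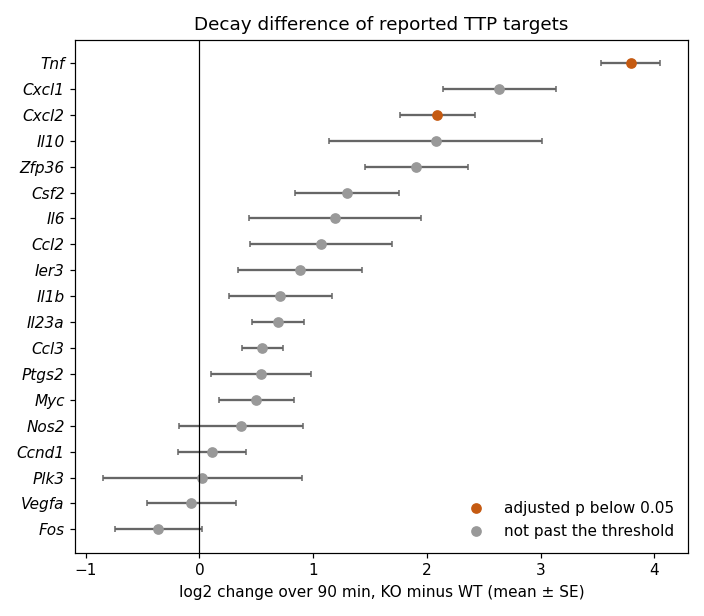
Decay difference at 90 min, KO minus WT, on the log2 scale (x axis) for the 19 measured reported TTP targets (y axis); points are model estimates, bars are SE, and orange marks an adjusted p below 0.05. Tnf at 3.79 and Cxcl2 at 2.09 are marked, and 17 of 19 points lie above 0, among them Zfp36, the targeted gene.

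The short-lived mRNAs of both genotypes were considered as a class. By the mean of both genotypes 92 genes were unstable, with a median log2 change of -1.70 in WT and -1.20 in KO. Of these, 1 gene, Tnf, fell less in KO past the threshold, and 2 did with the series as a block or without WT 90 min replicate 2. The decay difference was positive for 83 of the 92, with a median of 0.48 (0.35 in series A, where 71 were positive, and 0.67 in series B, where 72 were). Dusp2 was near the signal limit of 3.03 by 45 min in WT and KO (3.64 and 3.46), so its later fall was not measurable and it is given no half-life. The relative half-lives of Socs3 were 24.6 min in WT (19.2 to 34.3) and 35.2 min in KO (25.1 to 59.2). Cxcl2 does not belong to this set, because its mean change over both genotypes did not reach the limit. The definition leaves out an mRNA that hardly fell in KO unless its fall in WT was large, so the count can miss such genes. Defined by WT alone, 96 genes were unstable, and 2 of them fell less in KO past the threshold.

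**Figure D3:**
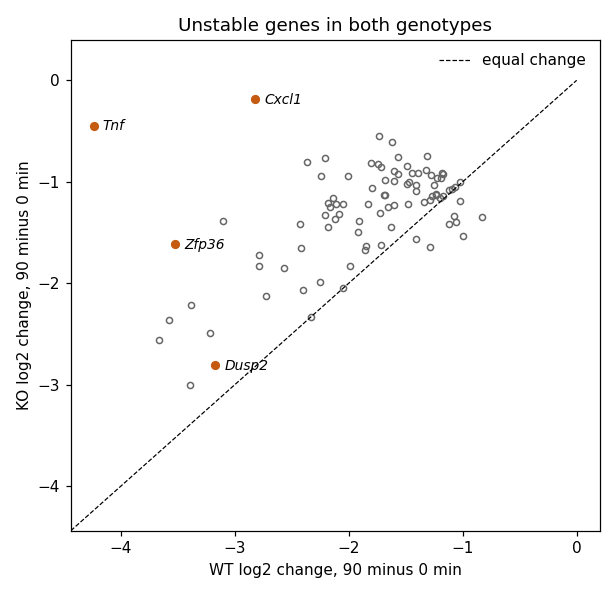
Log2 change from 0 to 90 min in KO (y axis) against that in WT (x axis) for the 92 unstable genes; each circle is the estimate for 1 gene, orange circles carry names, and the dashed line marks equal change. Tnf (-4.24 in WT and -0.45 in KO) and Cxcl1 (-2.82 and -0.18) lie far above the line, and Dusp2 (-3.17 and -2.81) close to it, where its signal had reached the limit of 3.03 or nearly so in both genotypes.

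At 45 min fewer genes passed than at 90 min. In WT, 13 genes fell and 0 rose in limma (142 had a higher signal at an unadjusted p below 0.05). Dusp2 fell by 2.97 ± 0.29, Zfp36 fell by 2.89 ± 0.32, Tnf fell by 2.37 ± 0.18, Csf2 fell by 2.12 ± 0.32 and Clec2d fell by 1.87 ± 0.28. In KO, 5 genes fell and 0 rose in limma (144 had a higher signal at an unadjusted p below 0.05). Dusp2 fell by 2.90 ± 0.29, Clec2d fell by 2.06 ± 0.28, Zfp87 fell by 1.51 ± 0.26, Rsl1 fell by 1.38 ± 0.22 and Gadd45b fell by 1.08 ± 0.18. The falls of Zfp87 and Rsl1 in KO ended at signals of 2.69 and 2.88, below the limit of 3.03, and those of Dusp2 (WT 3.64, KO 3.46) and of Csf2 in WT (3.38) close to it, so background limits these falls. The replicate block gave 25 lower and 1 higher in WT and 26 lower and 0 higher in KO, and the series block 32 and 1, and 28 and 0. Within series B there were 38 lower and 218 higher in WT and 39 lower and 0 higher in KO. Of the 256 WT genes 65 had the same sign in series A, and of the 39 KO genes all did.

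Single arrays moved the 45 min counts. In WT, 242 genes rose and 25 fell without WT 0 min replicate 3, and 1 rose without WT 90 min replicate 3. The genes that fell in WT numbered 4 and 3 without WT 0 min replicates 1 and 2, 4 without WT 45 min replicate 1, 2 or 3, 8 without WT 90 min replicate 1, and 7 without KO 0 min replicate 2 or KO 45 min replicate 1. In KO, 18 fell without WT 0 min replicate 3, 20 and 12 without KO 90 min replicates 2 and 3, and 8 without WT 90 min replicate 2. Between 1 and 3 fell in KO without WT 45 min replicate 2 or 3, WT 90 min replicate 1, KO 0 min replicate 1, 2 or 3, KO 45 min replicate 1, 2 or 3, or KO 90 min replicate 1. Csf2 lost its call in WT in 5 of 18 omissions and Clec2d in 3. In KO, Clec2d lost it in 2, Zfp87 in 11, Rsl1 in 7 and Gadd45b in 9.

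Of the reported TTP targets 4 of 19 fell in WT over 45 min (8 adjusted over the list alone), with a list median of -0.70 (camera adjusted p 4.32e-20, and adjusted p = 0.000237 with an estimated correlation). Of cytokines 3 of 21 fell (4 adjusted over the list alone), with a median of -0.28 (adjusted p 2.30e-05, and adjusted p = 0.00323 with an estimated correlation). Another 7 lists were lower at the preset correlation only. With medians in parentheses, their adjusted p with an estimated correlation were: chemokines (-0.13) 0.404, immediate early genes (-0.48) 0.0714, NF-kB feedback genes (-0.20) 0.404, MAP kinase phosphatases (-0.11) 0.220, survival regulators (-0.14) 0.220, respiratory chain genes (-0.09) 0.404, numbered zinc finger genes (-0.06) 0.883. Centring on ribosomal protein genes shifted all genes by 0.15 in this comparison, which exceeds the size of the medians of chemokines, MAP kinase phosphatases, survival regulators, respiratory chain and zinc finger genes, and the respiratory chain list was then lost (adjusted p 0.230). In KO at 45 min no list held with an estimated correlation. The adjusted p with an estimated correlation there were: reported TTP targets (-0.28) 0.0887, cytokines (-0.22) 0.0556, immediate early genes (-0.49) 0.0887, NF-kB feedback genes (-0.28) 0.290, MAP kinase phosphatases (-0.34) 0.0556, survival regulators (-0.34) 0.0556, deadenylation and decay genes (-0.16) 0.299, numbered zinc finger genes (-0.21) 0.104, fibroblast markers (0.22) 0.290.

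The decay difference at 45 min passed for Tnf alone, at 2.01 ± 0.26 (limma adjusted p 0.00472), with 1.84, 1.67 and 2.53 per replicate number; 0 genes had a negative difference past the threshold, against 113 at an unadjusted p below 0.05. The series block gave the same counts, and within series B the Tnf difference was 1.76 with an adjusted p of 0.0325. The call was lost with centring on ribosomal protein genes (1.81, adjusted p 0.610) or housekeeping genes (1.80, adjusted p 0.109) and without the arrays of replicate 1 (2.10) or replicate 2 (2.18). Without WT 0 min replicate 3, 79 genes had a negative difference. The reported TTP targets had a median of 0.41 (0.76 in series A and 0.24 in series B), with 1 of 19 past the threshold and 4 adjusted over the list alone (camera adjusted p 9.01e-08, and adjusted p = 0.0177 with an estimated correlation). That call was lost with an estimated correlation and the series as a block (adjusted p 0.103). Respiratory chain genes (median 0.18) were higher as a set, and numbered zinc finger genes (-0.20) and deadenylation and decay genes (-0.17) lower, with 0 members past the threshold in limma. Their adjusted p with an estimated correlation were 0.378, 0.827 and 0.827, and the first median is smaller than the shift of -0.20 under centring on ribosomal protein genes.

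Before the transcription block, at 0 min, 0 genes were higher and 0 lower in KO past the threshold in limma. The smallest adjusted p was 0.152, with 387 genes higher and 390 lower at an unadjusted p below 0.05. Tnf had a difference of 0.19, Cxcl1 of 0.19 and Cxcl2 of 0.29. The chemokine gene Ccl22 had -2.26 ± 0.43 (adjusted p 0.190), Cd83 -1.16 ± 0.26 and the mannose receptor gene Mrc1 1.43 ± 0.29, none past the threshold. The replicate block gave 19 genes higher and 13 lower, and the series block 23 and 13, with Ccl22 past the threshold (adjusted p 0.00638). Within series B 840 were higher and 101 lower, and of those 941 genes 342 had the same sign in series A; across genes the correlation of the 2 series was -0.08, where genes are not independent replicates. Without WT 0 min replicate 3 alone, 738 genes were higher and 77 lower, and without KO 90 min replicate 3, 1 was lower.

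Some lists differed at 0 min, with 0 members past the threshold over all genes tested in limma. Macrophage markers had a median of 0.35 in KO against WT (4 of 15 adjusted over the list alone), neutrophil markers 0.53 (1 of 4), sex-linked marker genes 0.43 (1 of 3) and numbered zinc finger genes 0.11. Ribosomal protein genes (41 measured) had a median of -0.25, respiratory chain genes (29) -0.19 and cell cycle genes (29) -0.24. In that order the adjusted p with an estimated correlation were 0.454, 0.467, 0.467, 0.778, 0.454, 0.207 and 0.778, so none held. Ribosomal protein genes had medians of -0.51 in series A and -0.08 in series B, cell cycle genes -0.75 and -0.10, neutrophil markers 1.08 and 0.34, and sex-linked genes -0.10 and 0.75. Centring on ribosomal protein genes moved the median of all genes by 0.30 at 0 min and gave 4 genes higher and 0 lower. The shift exceeds the size of the medians of respiratory chain and cell cycle genes. For the ribosomal protein list it only mirrors the list's own difference.

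The remaining lists were not called for the decay difference at 90 min, with 0 members past the threshold over all genes tested in limma. With the number measured, the median and the camera adjusted p, they were interferon-stimulated genes (29, 0.03, 0.633); the ZFP36 family and other 3' UTR binding proteins (13, -0.01, 0.808); deadenylation and decay genes (30, -0.03, 0.932). Cell type lists gave 0.15 for 14 antigen presentation genes (0.751), 0.22 for 6 dendritic cell markers (0.972), 0.21 for 3 B cell markers (0.633), -0.07 for 8 fibroblast markers (0.450), 0.04 for 15 macrophage markers (0.815) and -0.08 for 4 neutrophil markers (0.751). Metabolic and stress lists gave 0.17 for 13 cholesterol genes (0.815), 0.24 for 12 glycolysis genes (0.171), 0.11 for 20 hypoxia and stress genes (0.755), -0.07 for 16 p53 targets (0.751). The other lists gave 0.11 for 17 housekeeping genes (0.368), 0.10 for 26 secreted and membrane inflammatory effectors (0.296). Of the secreted and membrane effectors 4 fell in WT over 90 min and 1 in KO. T and NK cell markers (2 measured), mast cell markers (1 measured) and erythroid markers (0 measured) were too few to test.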

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

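The tests of a batch marked by the title numbers, of a weaker transcription block, of brightness within Tnf, Cxcl1 and Cxcl2 and all counts of other splits of the samples were chosen only after the result was seen. A decay difference between the genotypes past the limma threshold drew attention to Tnf, at 3.79 at 90 min and 2.01 at 45 min, and to Cxcl2, at 2.09 at 90 min. Cxcl1 passed with a block or within series B, and not otherwise among the settings run. Exact 2-sided permutation of the genotype labels within 0 and 90 min gave a difference as large in 40 of 400 labellings for Tnf (p = 0.1), 32 for Cxcl1 (p = 0.08) and 40 for Cxcl2 (p = 0.1). Each of these labellings kept or exchanged the 90 min labels whole, as 40 of the 400 do, so that a permutation p below 0.05 was out of reach for genes with like levels at 0 min.

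The slower fall of Tnf, Cxcl1 and Cxcl2 in KO was weighed against 3 technical explanations, of which a batch marked by the title numbers is argued against, since the lowest of the 9 differences by gene and replicate number was 1.53. A weaker transcription block in KO is argued against as the whole cause: over 89 genes outside the reported targets that were unstable by WT alone, the median ratio of the KO to the WT change was 0.655 (SD over replicate numbers 0.296), and over the 49 of them at least 1 above the signal limit in WT at 90 min 0.658, while Tnf had 0.105, Cxcl1 0.0653 and Cxcl2 -0.0554. Signals too bright to fall are argued against for Tnf as the whole cause. From 45 to 90 min its signal in KO moved by -0.09, against -2.37 in WT from 0 to 45 min (lowest difference by replicate number 1.81). The KO signal at 45 min lay -0.05, -0.42 and -0.04 from that in WT at 0 min in replicates 1, 2 and 3. The KO and WT 0 min arrays of series A read Tnf 0.03 ± 0.13 (SE) above the KO arrays of series B. The comparison of the series thus shows no room above the KO readings. However, the Tnf signal in KO went from 11.94, 12.04 and 12.10 at 0 min to 11.49, 11.85 and 11.40 at 90 min in replicates 1, 2 and 3. It was thus not held at a ceiling, and at 45 min it read no higher than the level from which WT fell by 2.37. For Cxcl1 the KO and WT 0 min arrays of series A read 0.958 ± 0.21 (SE) above the KO arrays of replicates 1 and 2. Array maxima were 9820 to 14337 in series A and 7379 to 9681 in series B. A higher reading in series A therefore need not show room in series B, and brightness stays open in replicates 1 and 2. It also stays open for Cxcl1 in replicate 3 and for Cxcl2, whose signals in KO at 45 min lay 0.1999 and 0.233 above those in WT at 0 min. The ratio of 0.716 for Nfkbia and Tnfaip3, as bright as Cxcl1, decides nothing, since each probe saturates at its own level. Loss of TTP-dependent decay, the biological explanation the design names, may account for the slower fall of the 3 genes. The design posed this explanation before the data, but attention was drawn to these 3 genes by their difference in the same data. It stays open, for Cxcl1 and Cxcl2 beside brightness.

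For the decay differences, 100 splits that relabelled the genotypes within each time were counted. Of these, 14 at 90 min and 8 at 45 min kept or exchanged the labels of the later time whole, and each of them gave at least the real number of genes, so the design is too small for a share below 0.05. In all, 17 of 100 splits gave at least the real 2 genes at 90 min, with 704 in the highest other, and 17 of 100 gave at least the real 1 slower gene among the unstable ones, with 17 in the highest other. At 45 min 13 of 100 gave at least the real 1 gene, with 4.52% of the tested genes in the highest other. Both of these highest splits exchanged WT 0 min replicate 3 with KO 0 min replicate 1, which lie in different title-number series, and so point to a structure of the samples. The split at 90 min also exchanged all 90 min labels. The split at 45 min also exchanged WT 45 min replicates 1 and 2 with KO 45 min replicates 2 and 3. With the series as a block the real split gave 3 genes at 90 min and 1 at 45 min. For the 5 lists at 90 min 59 of 100 splits gave as many (highest other 11), 46 of them among the 86 that mixed the later labels, and for the 4 lists at 45 min 62 of 100 did (highest other 11), 56 of them among 92.

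Features of the value table without a single gene name also carried a signal. Of 1929 such features, 812 of them with several symbols, 49 passed in WT at 90 min (1 higher and 48 lower), 24 in KO at 90 min and 15 in KO at 45 min, all of the last 2 groups lower.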

How the results depend on the processing

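Several settings were added after the data had been seen, namely the comparison averaged over the 3 times, the gene span correction alone and with the series block, the offset of 16, WT at 0 min represented by replicate 3 alone and the arrays of a genotype and number taken as a set. No called value of a named gene changed sign under any setting, and a filter on the mean over all arrays moved no count by over 1.5 times. The cause of a moved count was not tested, except that settings with fewer arrays hold less information. The larger side of the counts turned in WT at 90 min without WT 0 min replicate 3 (163 and 133) or without replicate 3 (765 and 613), in WT at 45 min for the same omissions (242 and 25, and 218 and 38), for the decay difference at 45 min without WT 0 min replicate 3 (1 positive and 79 negative), and over the 3 times with WT at 0 min by replicate 3 alone (32 and 53). Counts are given as higher and lower genes, and Tnf at 90 min kept its decay difference call throughout (3.63 to 3.88). Genes near the median signal are limited by background, since no detection calls were used here.

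The replicate number as a block gave 10 and 286 genes in WT at 90 min, 1 and 56 in KO at 90 min, 1 and 25 in WT at 45 min, 26 lower in KO at 45 min, 19 and 13 between genotypes at 0 min, 303 and 173 over the 3 times, and 2 slower unstable genes. The numbers do not pair the samples for WT at 90 min or the decay differences. For each array, deviations from the group means were correlated with those of arrays in other groups and averaged by replicate number. The mean was highest for the array's own number in 15 of 18 arrays, a hint from the data of shared structure. The block changed no gene call of the decay difference at 45 min. A random replicate number gave 7 and 227 in WT at 90 min, 45 lower in KO at 90 min, 1 and 24 in WT at 45 min, 17 lower in KO at 45 min, 198 and 103 over the 3 times, and 2 unstable genes. The series as a block gave 10 and 291, 1 and 60, 1 and 32, 28 lower, 23 and 13, 320 and 174, and 2 in the order of the replicate block.

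Without the filter on dim genes 5 genes were higher in WT at 90 min, 12 lower in KO at 90 min and 1 had a decay difference at 90 min. With all features per gene kept, and with trend and robust variance, 2 were higher in WT at 90 min. Centring on ribosomal protein genes gave 71 lower in WT at 90 min, 4 lower in WT at 45 min, 12 lower in KO at 45 min, 1 and 0 decay differences at 90 and 45 min, 4 higher at 0 min, and 1038 and 29 over the 3 times. Centring on housekeeping genes gave 35 lower in KO at 90 min, 4 lower in WT at 45 min, 11 lower in KO at 45 min, 1 and 0 decay differences and 27 lower over the 3 times. The median of all genes shifted under ribosomal centring by 0.11 in WT at 90 min, 0.15 in WT at 45 min, -0.10 and -0.20 for the decay differences at 90 and 45 min, 0.30 at 0 min and 0.19 over the 3 times. Under housekeeping centring it shifted by 0.16 in WT at 45 min, -0.16 and -0.21 for the decay differences and 0.15 at 0 min. Cyclic loess gave 4 higher in WT at 90 min, 11 lower in KO at 45 min and 1 decay difference at 90 min.

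The planned array weights could not be fitted, because their likelihood estimate stopped before convergence (weights of 0.159 to 9.04), and they are not counted among the settings. With the weights where the estimate stopped, calls rose to 1886 and 2107 in WT at 90 min, 7 and 105 in KO at 90 min, 1284 and 828 in WT at 45 min, 9 and 104 in KO at 45 min, 998 decay differences at 90 min (535 positive and the others negative), 210 and 786 decay differences at 45 min, 1970 and 1280 at 0 min, and 1602 and 803 over the 3 times. With only the arrays compared, 64 were lower in WT and 1 in KO at 90 min, and 1 had a decay difference. A minimum log2 change of 1 left 14 and 3 over the 3 times. A straight line over time gave 2 higher in WT and 11 lower in KO. Unstable genes defined by WT alone or at a limit of -0.5 had 2 slower members.

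The gene span correction gave 3 higher in WT at 90 min and 1 decay difference. With the series block it gave 14 and 293 in WT at 90 min, 2 and 69 in KO at 90 min, 1 and 25 in WT at 45 min, 30 lower in KO at 45 min, 25 and 14 at 0 min, 315 and 171 over the 3 times and 2 unstable genes. The offset of 16 gave 13 lower in KO at 90 min, 3 lower in KO at 45 min and 1 decay difference. WT at 0 min by replicate 3 alone gave 4 and 365 in WT at 90 min, 10 lower in KO at 45 min, 1 and 0 decay differences at 90 and 45 min and 32 higher over the 3 times. Over the 3 times, sets of equal genotype and number as a random effect gave 30 and 13, set means 2 and 0 (limma, with 401 and 226 at an unadjusted p below 0.05) and set means with the series as a term 242 and 99.

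An estimated correlation left higher lists at 0 in WT and KO at 90 min, KO at 45 min and at 0 min, 2 and 1 for the decay differences at 90 and 45 min, and lower lists at 4 in WT and 4 in KO at 90 min, 2 in WT and 0 in KO at 45 min, 0 for the decay difference at 45 min and 0 at 0 min. With the replicate block camera gave 1 higher list in WT at 45 min, 3 in KO at 45 min, 3 for the decay difference at 90 min and 5 lower at 0 min. With the replicate block and an estimated correlation, immediate early genes and survival regulators in WT at 90 min had an adjusted p of 0.0694, and the reported TTP targets 0.1002 for the decay difference at 45 min and 0.0576 over the 3 times. With the series block camera gave 1 and 3 at 45 min, 4 for the decay difference at 45 min and 5 lower at 0 min. With ribosomal centring it gave 4 higher for the decay difference at 45 min and 8 lower at 0 min.

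Leaving out single arrays or a whole replicate number, which leaves 2 arrays per group, gave these ranges. In WT at 90 min 0 to 765 genes were higher and 3 to 613 lower, and in KO at 90 min 0 to 1 and 0 to 63. In WT at 45 min the ranges were 0 to 242 and 1 to 38, and in KO at 45 min 0 to 0 and 0 to 39. Decay differences at 90 min ran from 1 to 5 positive and 0 to 2 negative, and at 45 min from 0 to 1 and 0 to 79. At 0 min they were 0 to 840 and 0 to 101, over the 3 times 1 to 500 and 0 to 97, and slower unstable genes 1 to 3.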

Other observations

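The comparison averaged over the 3 times, its genes, the use of sets of arrays, the dendritic cell test and all counts of other splits were chosen only after the data had been seen. Averaged over 0, 45 and 90 min, 90 genes were higher and 46 lower in KO than in WT macrophages (limma). Its SE and p treat the 9 arrays of a genotype as independent, although arrays of equal genotype and number deviate together between several of the times. With such sets of 3 arrays as a random effect 30 genes were higher and 13 lower. On the 6 set means 2 genes, Tnf and Cp, were higher and 0 lower (limma, with 401 and 226 at an unadjusted p below 0.05), and with the series as a term 242 were higher and 99 lower. Among the mRNAs with the slower fall described above, Tnf was higher by 2.13 ± 0.10, Cxcl1 by 1.59 ± 0.20 and Cxcl2 by 1.39 ± 0.13. The anti-inflammatory cytokine gene Il10 was higher by 2.08 ± 0.38 (adjusted p 0.0101), Ier3 by 1.69 ± 0.22 and the glycolytic regulator gene Pfkfb3 by 1.31 ± 0.30. The mannose receptor gene Mrc1 was higher by 1.12 ± 0.17, the phagocytic receptor gene Mertk by 0.76 ± 0.10, the lipoprotein gene Apoe by 0.96 ± 0.14, Pdpn by 0.97 ± 0.18, Pla2g7 by 0.89 ± 0.21 and the granulocyte growth factor receptor gene Csf3r by 1.00 ± 0.15. Each of these was higher in KO in 9 of 9 pairs of equal number and time. The phagocytic receptor gene Axl had -0.73 ± 0.13 (adjusted p 0.00760), higher in KO in 1 of 9 pairs, and the scavenger receptor gene Msr1 had 0.31 ± 0.17 (adjusted p 0.521), not past the threshold. Ccl22, which encodes a chemokine for T cells, had -2.14 ± 0.25 (adjusted p 0.000294) and Cd83 -1.13 ± 0.15 (adjusted p 0.000766), both higher in KO in 0 of 9 pairs. Ccl17 had -1.86 ± 0.46 (adjusted p 0.0602, with the series block 1.88e-06) and Cx3cl1 -1.35 ± 0.35 (adjusted p 0.0695, with the series block 1.34e-05). Of the genes called here, Pfkfb3, Pla2g7 and Axl lost their call with random sets (adjusted p 0.0725, 0.101 and 0.0596), and all but Tnf lost it on the set means without the series term (adjusted p 0.0798 to 0.669).

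By list in this comparison, 6 of 19 reported TTP targets were higher (8 adjusted over the list alone; median 0.37, camera adjusted p 1.79e-10, and adjusted p = 0.00513 with an estimated correlation, but 0.0544 with the series block as well and 0.175 on the set means). Macrophage markers had 4 of 15 higher (6 adjusted over the list alone; median 0.22), with an adjusted p = 0.147 with an estimated correlation. Cytokines had a median of 0.18 and neutrophil markers 0.53, with adjusted p of 0.0749 and 0.333 with an estimated correlation; the cytokine list was lost when centred on ribosomal protein genes (adjusted p 0.260). Cell cycle, respiratory chain and ribosomal protein genes had medians of -0.22, -0.09 and -0.16, and adjusted p of 0.426, 0.147 and 0.147 with an estimated correlation. The shift of 0.19 under centring on ribosomal protein genes exceeds the size of the respiratory chain median. For the ribosomal protein list it only mirrors the list's own difference. That centring gave 1038 genes higher and 29 lower. The replicate block gave 303 and 173, the series block 320 and 174, and series B alone 500 and 97. Without WT 0 min replicate 3, 404 genes were higher and 95 lower. The higher genes numbered 59 without WT 0 min replicate 1 or 2 or WT 45 min replicate 3, 57 without WT 45 min replicate 2 and 55 without KO 0 min replicate 3. The lower genes numbered 24 without WT 45 min replicate 2 or KO 0 min replicate 3, 27 without WT 45 min replicate 3, WT 90 min replicate 1 or KO 90 min replicate 3, 28 without KO 90 min replicate 1 and 30 without WT 0 min replicate 2.

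Explanations for the 136 genes higher or lower in KO over the 3 times were tested as follows. The region around Zfp36 inherited with the knockout is argued against as the whole cause, since 5.15% of these genes (7 of 136: Alkbh6, Apoe, Axl, Gmfg, Mrps12, Pou2f2 and Snrpd2) lie within 15 Mb of Zfp36, against 2.04% of tested genes (Fisher's exact p = 0.0211, 2-sided); it stays open for those 7. Fewer dendritic cells in KO stay open as the reason for low Ccl17 and Ccl22 (mean -2.00): the 6 measured dendritic markers had a median of -0.102 with 1 past the threshold, Cd83, but Zbtb46 and Ccr7 lay near the signal limit, and macrophages can also express Itgax, Bst2 (mean log2 intensity 8.23), Fscn1 and Cd83. A candidate explanation is a response to the higher Il10 mRNA: an IL-10 response list of 8 measured genes was higher (camera p 4.24e-06, and p = 0.0454 with an estimated correlation, or 0.0975 on the set means), with 7 of 8 positive, a median of 0.45 and 1 past the threshold, Fcgr1, which is also a macrophage marker (adjusted p 0.231 with random sets). At 0 min, before transcription was blocked, Il10 itself had 0.83 ± 0.66 (adjusted p 0.798, with 1.15, 1.25 and 0.09 in replicates 1, 2 and 3) and the list a median of 0.32 with 6 of 8 positive (p = 0.0122, and p = 0.247 with an estimated correlation), and slower decay of some of these mRNAs in KO may contribute as well, so the tests leave both open.

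The 941 genes called between KO and WT at 0 min within series B were weighed as a further pattern. A bias related to gene span is argued against as the whole cause, since 745 genes were called after correction for span, 645 of them shared with the 941. A shift of the WT 0 min arrays of that series could be the source: 66.3% of the called genes had the same sign at 45 and 90 min over all arrays, but the share ran from 22.7% to 88.9% between replicate numbers, so it cannot be told apart from a genotype effect.

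For the other counts, 3 arrays against 3 give 10 splits, too few for a share below 0.05. These splits relabel arrays freely, also where the replicate numbers were taken to pair the samples. WT at 90 min had 126 genes, and 2 of 10 splits gave as many, the highest other 307; that split exchanged replicate 3 of the 0 and 90 min groups and so follows the title-number series, and with the series as a block 10 genes were higher and 291 lower. The 10 lists there were reached in 1 of 10 (highest other 9). In KO at 90 min the 23 genes and 13 lists were each reached in 1 of 10 (highest other 0 and 11), and in WT at 45 min so were the 13 genes and 9 lists (highest other 0 and 4). In KO at 45 min the 5 genes were reached in 1 of 10 (highest other 0) and the 9 lists in 2 of 10 (highest other 14). At 0 min all 10 splits reached the real count of 0, with 1028 genes in the highest other, which exchanged WT 0 min replicate 3 with KO 0 min replicate 1 and points to a structure of the samples; the 7 lists were reached in 2 of 10 (highest other 9). The comparison averaged over the 3 times has 10 splits as well, because arrays of equal genotype and number deviate together between several of the times and were relabelled as a set. Of these, 3 of 10 gave as many as the real 136 genes, with 1272 in the highest other, which exchanged WT replicate 3, of series A, with KO replicate 1, of series B, and so points to a structure of the samples; with the series as a block 320 genes were higher and 174 lower. Relabelled at each time on its own, which breaks up these sets, 1 of 100 splits gave as many, with 30 in the highest other.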
